A study of Mus musculus with 36 samples.

How the data were processed

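RNA abundance was measured by sequencing in mouse embryonic fibroblast (MEF) lines that carry 0, 1 or 2 copies of the N129D knock-in allele of Tbk1. Per the labels, RNA was purified with RNeasy Plus columns, and 500 ng of total RNA per sample entered a TruSeq Stranded mRNA preparation. Per the design text, the libraries were sequenced on an Illumina HiSeq instrument. The strand setting used for counting, the read length and the annotation release are not given in the sources used here.

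The deposited values are expected counts per gene, that is, estimated read counts that need not be whole, given by the authors in 1 table per library. STAR, RSEM and the genome build mm10 are named without versions or settings, per the submitters' processing notes; the versions are not given in the sources used here. RSEM shares out reads that match several genes, so members of families with near-identical copies, such as Ifit3 and Ifit3b, are less certain than single-copy genes. Between 6.11% and 13.4% of the values in a library were not whole. Each table held 49585 genes, of which 49326 matched GENCODE vM21 by Ensembl identifier. That annotation is on GRCm38, the assembly called mm10, and gave the gene names and coordinates.

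The expected counts were rounded to whole numbers. The total per library ran from 3689177 to 14879261 counts in the 30 libraries without a density label, from 16474077 to 22756901 at high density and from 5391426 to 6308011 at low density. A gene listed at 0 in a whole group was set against a floor of 3 counts over that group, and its fold, from counts pooled over the lines of each group, is given as a lower bound. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

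Groups were taken from the sample titles: wild type (WT, 3 lines), heterozygous (het, 4 lines) and homozygous (hom, 3 lines), each untreated, given poly(I:C) for 4 h, or given antimycin and oligomycin (AO) for 4 h. The 30 libraries of these 9 groups were fitted together in edgeR 4.0.16 under R 4.3.3, with TMM normalization, filterByExpr (minimum count 10, minimum total 15) and 1 coefficient per group. The quasi-likelihood F test was used, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 with no fold limit. This left 13364 genes. The comparisons were each treatment against untreated cells within a genotype, hom and het against WT within a treatment, the difference of each response from that in WT, and a linear trend over the number of N129D alleles. The 9 libraries of WT line E1.5, 6 of them with a density label, were fitted with terms for treatment and density over 12229 genes. Values per group are CPM (counts scaled to the size of each library as adjusted by TMM) with SD over lines, and log2 fold changes carry their SE. Peaks and means over libraries of chondrocyte, smooth muscle, erythroid and Hox markers were scaled to the library total without TMM.

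The labels name the same line in each treatment, so the libraries of 1 line share an embryo and are paired. The deviations of paired libraries from their group means correlated by 0.342 to 0.765 across genes over 30 pairs. A fit with the line as a replicate block was an alternative to the main one. No pair of libraries differed by as little as sampling noise: the chi-square per degree of freedom between libraries of a group was 5.61 to 65.7. The labels name separate lines. P-values of the main fit rest on the spread between libraries within groups, pooled over all 9 groups, het lines included. This fit takes the libraries of 1 line as independent, although their deviations correlate. Its p-values thus do not measure the spread between the compared lines alone.

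A total of 24 gene lists and 11 marker lists were fixed before the data were examined, as were the designs, the alternatives other than those named as added, and the rule for named genes. Each list was counted over all genes tested and again adjusted over the list alone, and tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 and again with an estimated correlation. Adjusted p-values of camera were taken over all lists of a kind and all comparisons together. Up to 30 genes per main comparison were named: the 8 largest changes per direction (5 in the other comparisons) among genes that passed, with a mean log2 CPM of at least 1 and the same direction in every line, or with no overlap between genotypes; the 3 members of each list with the smallest p; and a fixed set of genes.

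The alternatives were RLE factors in place of TMM, no filter on low counts, DESeq2 1.42.0, the replicate block, a fit on the compared groups alone, the first part of the line name (E1 or E2) as a covariate, Y-linked expression as a covariate, and leaving out each line in turn. Leaving out pairs of lines that stood apart was added after the data were seen. The test was tried on simulated counts with sets of 50 genes changed by known folds. For hom against WT under poly(I:C) it recovered 64% of 50 genes changed 2-fold and 90% of 50 changed 4-fold, with 5 false calls among 176, over 13364 genes. The simulated libraries were independent of each other, without lines shared between treatments or lines that stood apart. The changed genes were drawn from the better expressed ones, so these shares may not hold for the real libraries.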

Results

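The deposited data describe mRNA levels in embryonic fibroblasts, mesenchymal cells grown from mouse embryos, of 3 Tbk1 genotypes. Tbk1 encodes a kinase that phosphorylates IRF3 downstream of sensors of foreign nucleic acid and also phosphorylates receptors of selective autophagy such as optineurin and p62. The knock-in allele N129D changes 1 amino acid of this kinase. WT lines E1.5, E2.1 and E2.7, het lines E1.3, E2.5, E2.6 and E2.8, and hom lines E1.4, E2.2 and E2.9 were each left untreated, given poly(I:C), a synthetic double-stranded RNA, for 4 h, or given AO for 4 h. Antimycin blocks respiratory complex III and oligomycin blocks ATP synthase, and the pair is used to trigger the removal of damaged mitochondria. The design text states replicates in fours, which the het groups have; the WT and hom groups have 3 lines each. A further 6 libraries came from WT line E1.5 at high or low density, 1 per density and treatment. Depth was 3689177 to 14879261 counts in the 30 libraries without a density label.

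Tbk1 mRNA, from the edited gene on chromosome 10 (121546455 to 121586787, minus strand, GRCm38), stood at 45.4 ± 5.59 CPM in untreated WT lines (SD, n = 3), 48.8 ± 0.973 CPM in het lines (SD, n = 4) and 45.1 ± 3.98 CPM in hom lines (SD, n = 3). Under poly(I:C) it stood at 38.6 ± 3.59, 43.9 ± 8.73 and 37.1 ± 1.55 CPM in the same order, and under AO at 68.3 ± 2.5, 67.5 ± 7.37 and 67.3 ± 9.89 CPM. The log2 difference of Tbk1 between hom and WT lines was -0.01 ± 0.14 (SE) untreated, -0.06 ± 0.14 under poly(I:C) and -0.02 ± 0.14 under AO, and none passed the test. A substitution of 1 amino acid need not alter the mRNA level, so these values do not check the genotype labels.

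The first comparison asked how WT fibroblasts responded to double-stranded RNA. Poly(I:C) induced Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774): the gene had no counts in untreated WT lines and reached a mean of 18.5 ± 7.98 CPM (SD, n = 3; adjusted p = 0.00114). Pooled over the lines, its 322 counts made 19 CPM, at least 114-fold higher than a floor of 3 counts over the untreated group (0.167 CPM). The chemokine gene Cxcl10 rose from 86.5 ± 11.9 to 1164 ± 169 CPM and the cytokine gene Il6 from 0.8 ± 0.342 to 20.5 ± 7.44 CPM. Of 9 genes in the list of interferons and antiviral chemokines 6 rose, and 8 rose when adjusted over the list alone, with a median log2 change of 5.19. In the list of NF-kB and inflammatory genes 15 of 36 rose, 18 adjusted over the list alone, among them Ccl2 by 3.55 ± 0.65 (log2, SE), Tnfaip3 by 2.42 ± 0.50 and Nfkbia by 1.81 ± 0.35, the latter pair encoding inhibitors of NF-kB. Of 63 interferon-stimulated genes 8 rose, 29 adjusted over the list alone, with a median of 1.71. Mx2, annotated as a polymorphic pseudogene, rose by 4.52 ± 1.04 and Oasl1, coding for an antiviral protein, by 3.12 ± 0.68. Isg15 was 1.38 ± 0.69 higher without passing (adjusted p = 0.318) in the main fit, which does not use the pairing by line. Among immediate-early genes 9 of 27 rose, 16 adjusted over the list alone, with Zfp36 up by 1.71 ± 0.24. Gbp5, Trim17 and Neurl3 were further genes with large rises, of 5.60 ± 1.04, 4.91 ± 0.98 and 4.88 ± 0.81.

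Among the 8 genes with the largest falls in WT cells under poly(I:C), 4 were annotated as non-coding and 4 as protein-coding, and non-coding RNAs were not tested as a group. Neat1, the scaffold of nuclear paraspeckles, dropped from 182 ± 30.3 to 53.9 ± 13.9 CPM (SD, n = 3), Meg3 from 42.4 ± 10.6 to 10.8 ± 3.19 CPM, and Firre from 20.1 ± 3.9 to 6.43 ± 0.258 CPM. Mir17hg, the host transcript of a microRNA cluster, changed by -2.04 ± 0.31 (log2, SE), Spaca6 by -2.07 ± 0.34, Gm12258 by -1.80 ± 0.38, Klhl24 by -1.70 ± 0.29 and Dynlt1c by -1.64 ± 0.41. None of the 25 cholesterol synthesis and uptake genes passed, with a median of 0.63. In total 424 genes passed, 169 higher and 255 lower.

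Camera ranked the interferon-stimulated genes (adjusted p = 2.24e-24), the NF-kB and inflammatory genes (2.85e-14), the interferons and antiviral chemokines (8.15e-08), the immediate-early genes (2.39e-15) and the cholesterol synthesis and uptake genes (1.31e-05) above other genes in WT cells. With an estimated correlation the immediate-early genes kept an adjusted p = 0.0129, while the adjusted p was 0.676 for the interferon-stimulated genes, 0.421 for NF-kB and inflammatory genes, 0.331 for interferons and antiviral chemokines and 0.945 for cholesterol synthesis and uptake genes with an estimated correlation. With the line as a replicate block 2077 genes passed, including 62 of the interferon-stimulated genes (adjusted p = 0.0242 with an estimated correlation) and 22 of the cholesterol synthesis and uptake genes (0.0289). The count of 424 fell to 9 without line E1.5, 59 without E2.1 and 49 without E2.7. It was 673 with DESeq2, 1578 in the compared groups alone and 170 with no filter.

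**Figure D1:**
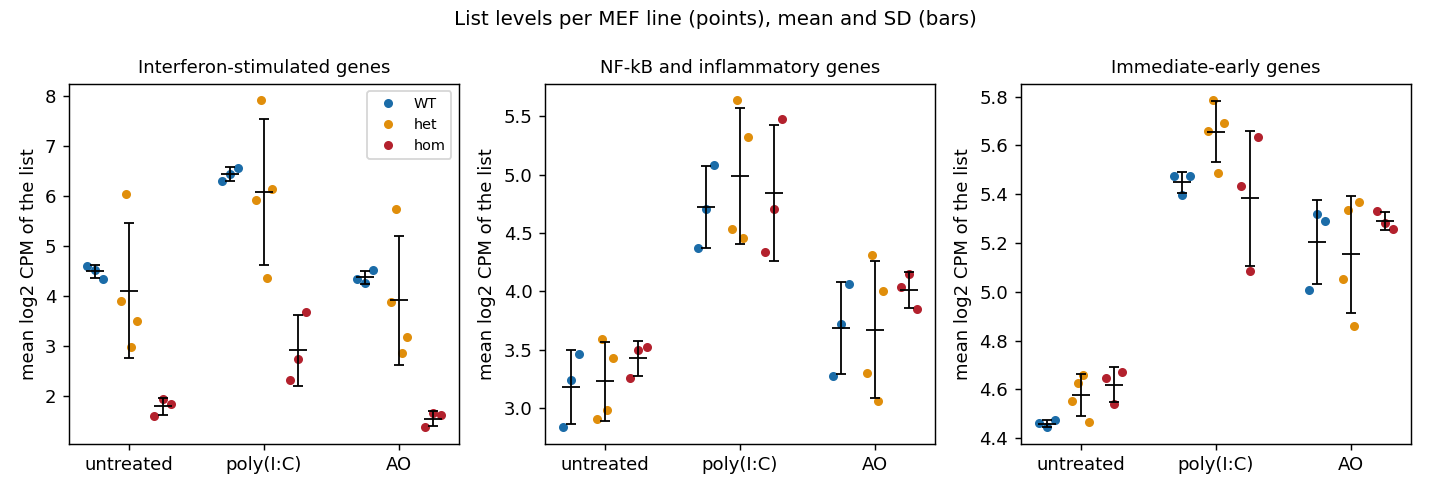
Mean log2 CPM (y axis) of 3 gene lists in each line, by treatment (x axis) and genotype (colour), with the mean and SD as bars. Interferon-stimulated genes of the 3 hom lines lay between 1.61 and 1.94 untreated, below the 3 WT lines at 4.35 to 4.61, while the levels of NF-kB and inflammatory genes overlapped between genotypes.

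In het lines poly(I:C) moved several of the genes named above in the same direction as in WT lines. The overlap of the leading genes was not counted. Ifnb1 had no counts untreated and reached a mean of 21.9 ± 19.8 CPM (SD, n = 4). Pooled over the lines it made 24.8 CPM, at least 231-fold higher than the floor of 0.107 CPM. Il6 rose by 5.21 ± 0.60 (log2, SE) and Cxcl10 by 4.27 ± 0.64, and Meg3, Mir17hg, Spaca6 and Firre changed by -1.84 ± 0.33, -1.79 ± 0.27, -1.77 ± 0.29 and -1.73 ± 0.22. Of the interferon-stimulated genes 19 of 63 rose (40 adjusted over the list alone; camera adjusted p = 1.08e-32, 0.524 with an estimated correlation), and of the NF-kB and inflammatory genes 19 of 36 (25 adjusted over the list alone; 5.83e-24, 0.15 with an estimated correlation). In total 619 genes passed, 296 higher and 323 lower. With lines as a replicate block 2368 passed; 102 did in the compared groups alone, 309 with no filter, 192, 290 and 121 without E1.3, E2.5 and E2.8, and 788 without E2.6.

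Hom lines were given poly(I:C) in the same way. Of the NF-kB and inflammatory genes 10 of 36 rose, 23 adjusted over the list alone (camera adjusted p = 5.61e-20, 0.228 with an estimated correlation), among them the chemokine genes Cxcl2 by 4.73 ± 0.84 and Cxcl1 by 3.62 ± 0.89 (log2, SE) and Tnfaip3 by 2.48 ± 0.50. Cxcl10 rose from 9.6 ± 5.69 to 134 ± 80.3 CPM and Ccl5 from 1.08 ± 0.149 to 12.6 ± 9.2 CPM (SD, n = 3). Ifnb1 gathered 5 counts over the 3 treated hom libraries, 0.265 ± 0.267 CPM, and did not pass (adjusted p = 0.39). None of the 63 interferon-stimulated genes passed in edgeR, over all genes or adjusted over the list alone, although their median was 1.21 (1.20 with genes at 0 set to their bound; camera adjusted p = 0.00112, 0.974 with an estimated correlation). Of the immediate-early genes 5 of 27 rose, 11 adjusted over the list alone, and Meg3, Spaca6 and Rhebl1 changed by -1.75 ± 0.38, -1.63 ± 0.34 and -1.63 ± 0.31.

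In total 168 genes passed in hom lines under poly(I:C), 71 higher and 97 lower. With lines as a replicate block 1274 passed, including 31 interferon-stimulated genes (camera adjusted p = 3.6e-15, 0.289 with an estimated correlation) and 29 NF-kB and inflammatory genes (0.0277 with an estimated correlation). The count was 349 with DESeq2, 37 with no filter, 0 in the compared groups alone, 559 without E1.4, 3 without E2.2 and 0 without E2.9. Libraries of E2.9 held macrophage transcripts, and whether these bear on the count was not tested.

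The second treatment asked how the cells responded to mitochondrial damage. In WT lines AO raised Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, from 69 ± 9.62 to 503 ± 121 CPM (SD, n = 3; chromosome 8, 75093621 to 75100589), and Gdf15, a secreted stress cytokine, from 1.19 ± 1.07 to 8.95 ± 3.72 CPM. Sqstm1, which encodes the autophagy receptor p62, rose from 383 ± 21.9 to 1028 ± 8.83 CPM, Optn by 0.67 ± 0.21 (log2, SE, adjusted p = 0.0469) and Tbk1 itself by 0.59 ± 0.14 (adjusted p = 0.00888). Of 39 integrated stress response genes 11 rose, 18 adjusted over the list alone, with a median of 0.77. Ppp1r15a rose by 2.36 ± 0.28, Ddit3 by 1.76 ± 0.37 and the amino acid transporter subunit gene Slc3a2 by 1.51 ± 0.25. Of 37 lysosomal genes 10 rose, 13 adjusted over the list alone with 1 lower, among them Flcn by 1.33 ± 0.18, Rragc by 1.02 ± 0.14 and Atp6v1b2, a subunit of the proton pump, by 0.97 ± 0.13. Of 20 aminoacyl-tRNA synthetases 5 rose, 9 adjusted over the list alone with 1 lower, and of 27 immediate-early genes 8 rose, 14 adjusted over the list alone.

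Of 32 G2 and mitosis genes 15 fell in WT lines under AO, 20 adjusted over the list alone, with Kif2c down from 142 ± 10.7 to 78.4 ± 12.7 CPM and Ccna2 from 330 ± 11.9 to 226 ± 14.9 CPM (SD, n = 3). Txnip, which encodes a brake on glucose uptake, dropped from 63.4 ± 11 to 8.83 ± 1.49 CPM, Bmf, a member of the apoptosis regulators of the BCL2 family, changed by -3.07 ± 0.79 (log2, SE), Medag by -3.06 ± 0.71, Gas1 by -2.57 ± 0.73 and Dnm3os by -2.45 ± 0.29. None of the 63 interferon-stimulated genes passed in edgeR, and their median was -0.11. With lines as a replicate block 5 fell. In total 1022 genes passed, 565 higher and 457 lower.

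Camera gave an adjusted p = 2.85e-16 for the G2 and mitosis genes (0.0499 with an estimated correlation), 2.32e-10 for the integrated stress response genes (0.773 with an estimated correlation), 1.36e-09 for the lysosomal genes (0.116), 5.08e-06 for the aminoacyl-tRNA synthetases (0.676) and 1.39e-08 for the immediate-early genes (0.0671). With lines as a replicate block 3045 genes passed in WT lines, and the adjusted p with an estimated correlation was 0.0107 for G2 and mitosis genes and 0.0107 for lysosomal genes. The count of 1022 was 2270 in the compared groups alone, 645 with no filter, and 259, 196 and 231 without E1.5, E2.1 and E2.7.

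**Figure D2:**
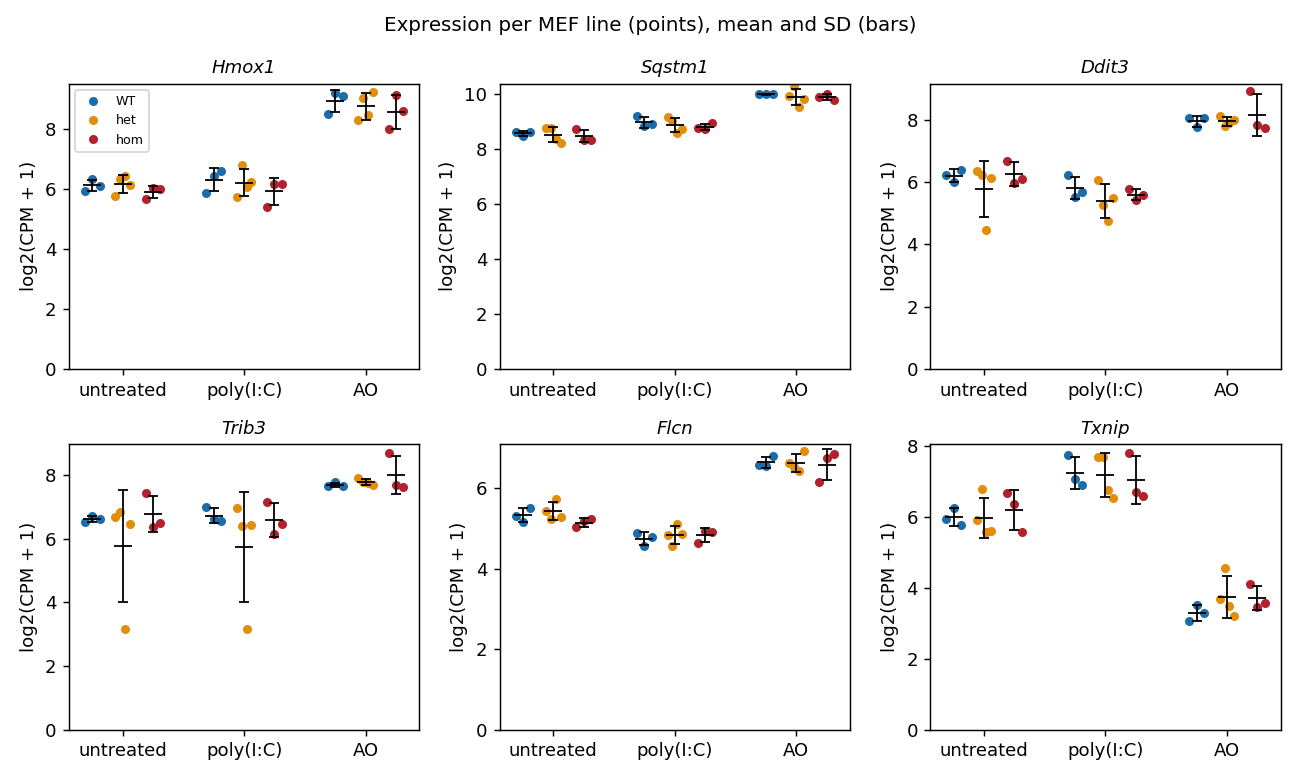
Expression of Hmox1, Sqstm1, Ddit3, Trib3, Flcn and Txnip as log2(CPM + 1) (y axis) in each line, by treatment (x axis) and genotype (colour), with the mean and SD as bars. Sqstm1 under AO averaged 1028, 978 and 954 CPM in WT, het and hom lines; 1 het line, E2.6, lay far below the others for Trib3 without AO.

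The other lists were counted in the same way under AO in WT lines. Counts of members that rose and fell were 4 and 1 of 37 autophagy and mitophagy genes, 4 and 0 of 25 dsRNA sensing and TBK1 signalling components, 3 and 0 of 25 ER unfolded protein response genes, 2 and 0 of 15 mitochondrial unfolded protein response genes, and 3 and 0 of 36 NF-kB and inflammatory genes. They were 1 and 2 of 19 glycolysis genes, 2 and 2 of 19 hypoxia-response genes, 2 and 1 of 21 NRF2 targets, 1 and 1 of 22 p53 targets, 2 and 1 of 30 S-phase and DNA replication genes, and 1 and 0 of 16 heat shock genes. They were 1 and 0 of 20 YAP and TEAD targets, 0 and 1 of 19 actin and SRF genes, and 0 and 0 of 32 fibroblast extracellular matrix genes, 25 cholesterol synthesis and uptake genes, 13 mitochondrially encoded mRNAs, 54 nuclear oxidative phosphorylation genes and 9 interferons and antiviral chemokines. Adjusted over the list alone the counts were 6 and 2 for autophagy and mitophagy genes, 5 and 1 for dsRNA sensing and TBK1 signalling components, and 3 and 1 for p53 targets. With lines as a replicate block the counts that rose and fell were 8 and 1 for NF-kB and inflammatory genes, 7 and 3 for dsRNA sensing and TBK1 signalling components, 5 and 1 for ER unfolded protein response genes, 8 and 5 for p53 targets, 0 and 9 for actin and SRF genes and 0 and 8 for fibroblast extracellular matrix genes. Hmox1 and Txnrd1 (0.81 ± 0.18) rose while G6pdx changed by -0.55 ± 0.15 within the NRF2 targets, and Vegfa rose by 1.35 ± 0.36 while Narf changed by -1.31 ± 0.26 within the hypoxia-response genes.

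Under AO several of the genes named above moved in the same direction in het and hom lines as in WT lines. The overlap of the leading genes was not counted. In het lines Hmox1 rose by 2.64 ± 0.28 (log2, SE), Gdf15 by 3.24 ± 0.55, Sqstm1 by 1.38 ± 0.15 and Tbk1 by 0.47 ± 0.12, while Txnip changed by -2.31 ± 0.38 and Medag by -2.90 ± 0.62. In hom lines Hmox1 rose by 2.76 ± 0.33, Gdf15 by 3.28 ± 0.62, Sqstm1 by 1.42 ± 0.17 and Tbk1 by 0.58 ± 0.14, while Txnip changed by -2.62 ± 0.45 and Medag by -3.66 ± 0.77. Of the integrated stress response genes 18 rose in het and 15 in hom lines (25 and 20 adjusted over the list alone; adjusted p = 0.581 and 0.816 with an estimated correlation). Of the lysosomal genes 11 rose in each genotype (15 and 17 adjusted over the list alone; 0.116 with an estimated correlation in each), and of the G2 and mitosis genes 16 fell in each (22 adjusted over the list alone in each; 0.0499 and 0.0601 with an estimated correlation). In total 1483 genes passed in het lines, 825 higher and 658 lower, and 1744 in hom lines, 983 higher and 761 lower. With lines as a replicate block the counts were 3663 and 3932. Het counts were 719, 748 and 515 without E1.3, E2.5 and E2.8. Hom counts were 802 without E2.2, 744 without E2.9, 1116 with no filter and 3 in the compared groups alone.

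The comparison of genotypes asked what the N129D allele did to basal and induced expression. Without treatment the interferon-stimulated genes stood far lower in hom than in WT lines. Ifit1 (chromosome 19, 34640871 to 34650009) stood at 124 ± 18.3 CPM in WT and 2.63 ± 1.97 CPM in hom lines, and the chemokine gene Ccl5 (chromosome 11, 83525778 to 83530518) at 33 ± 14.5 and 1.08 ± 0.149 CPM (SD, n = 3). These 2 genes, at -5.56 ± 0.97 and -4.91 ± 0.84 (log2, SE), each with an adjusted p = 0.0473, were the only ones of 13364 to pass. Adjusted over the list alone 46 of the 63 interferon-stimulated genes were lower and none higher, with a median of -2.79 (-2.76 with genes at 0 set to their bound), against 1 over all genes. Isg15 differed by -4.19 ± 0.81 (adjusted p = 0.0883) and Rsad2 by -6.29 ± 1.76 (0.721). Tnfaip3 differed by -0.01 ± 0.49 and no member of the NF-kB and inflammatory genes passed.

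Camera gave the interferon-stimulated genes an adjusted p = 2.1e-38 in untreated hom against WT lines (0.421 with an estimated correlation). Both passing genes were lost when any WT or hom line was left out, the count then being 0 each time. It was 33 with DESeq2, 52 in the compared groups alone, and 0 with no filter or with either covariate. The 52 genes were all lower in hom lines. The fit on the compared groups alone leaves out the other treatments and the het lines, whose wide spread enters the main fit.

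Under poly(I:C) 25 genes passed between hom and WT lines, all 25 lower in hom lines. Ifnb1 stood at 18.5 ± 7.98 CPM in WT and 0.265 ± 0.267 CPM in hom lines (SD, n = 3), a log2 difference of -5.94 ± 0.92 (SE, adjusted p = 0.0253). Mx2 differed by -6.45 ± 1.20, Ifit3b by -5.84 ± 1.11, Ifit3 by -5.30 ± 1.08, Oasl1 by -5.17 ± 0.78, Ifit1 by -4.93 ± 0.88, Oas1b by -4.31 ± 0.82, Ddx60 by -3.76 ± 0.79, Isg15 by -3.76 ± 0.77 and Ifih1, which encodes the RNA sensor MDA5, by -3.29 ± 0.56. Of the 63 interferon-stimulated genes 13 were lower, 59 adjusted over the list alone, with a median of -3.35. Of 9 interferons and antiviral chemokines 2 were lower, Ifnb1 and Ccl5, and 7 adjusted over the list alone. Among 36 NF-kB and inflammatory genes 1 was lower, Il6 at 20.5 ± 7.44 against 2.65 ± 1.39 CPM, while Tnfaip3 differed by 0.05 ± 0.47 and Nfkbia by 0.21 ± 0.33 without passing. The cell-cycle gene Ccne1 and the stress-response gene Ppp1r15a were also lower, by -1.26 ± 0.23 and -1.34 ± 0.27.

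Camera gave an adjusted p = 1.08e-105 for the interferon-stimulated genes (0.0514 with an estimated correlation) and 1.9e-18 for the interferons and antiviral chemokines (0.0499 with an estimated correlation) under poly(I:C). The count of 25 was 107 with DESeq2, 110 in the compared groups alone, 52 with E1 or E2 as a covariate and 5 with no filter, and it fell to 3 without E2.1 and to 0 without any other WT or hom line. Without E2.9 and het line E2.6, whose libraries held macrophage transcripts, 20 genes passed, 14 of them shared, and without E1.4 and E2.6 17 passed, 11 of them shared; both were added after the data were seen.

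**Figure D3:**
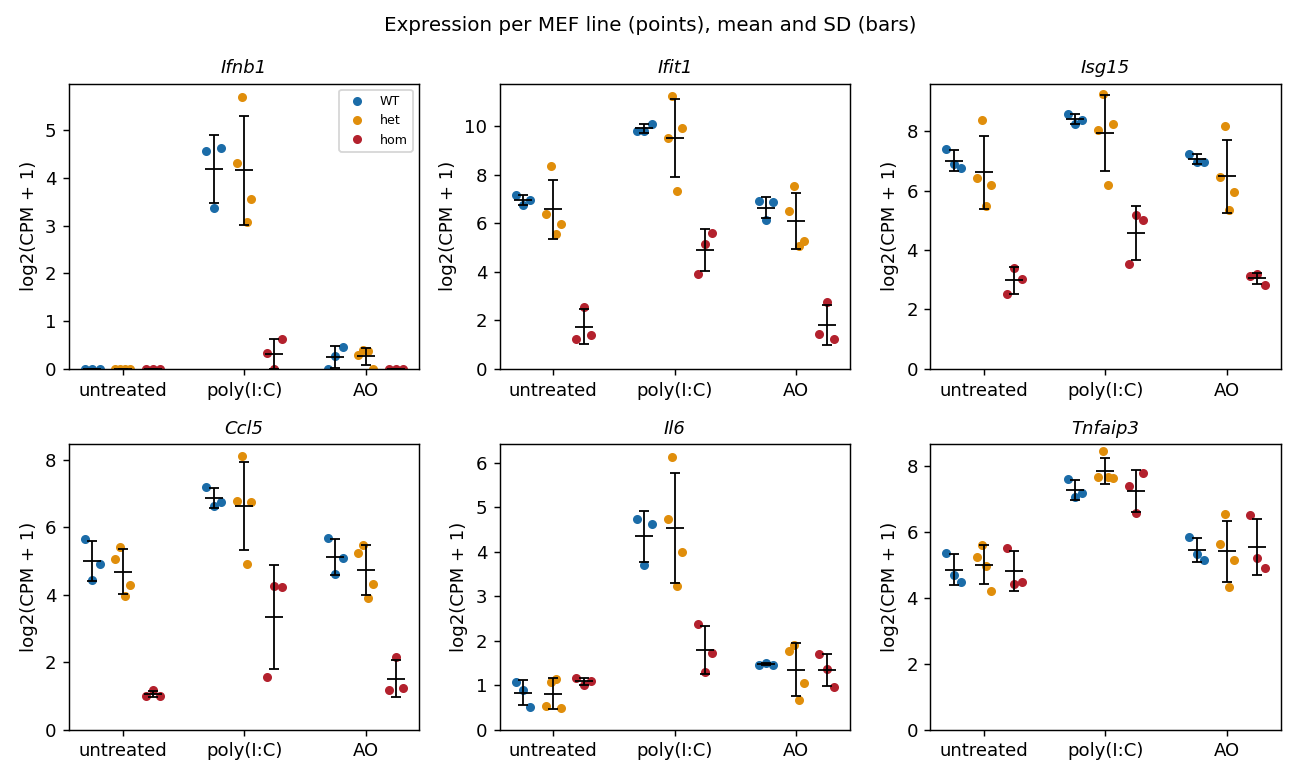
Expression of Ifnb1, Ifit1, Isg15, Ccl5, Il6 and Tnfaip3 as log2(CPM + 1) (y axis) in each line, by treatment (x axis) and genotype (colour), with the mean and SD as bars. Ifit1 under poly(I:C) averaged 963 CPM in WT and 31.9 CPM in hom lines, while Tnfaip3 averaged 155 and 159 CPM.

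Under AO the interferon-stimulated genes were again lower in hom than in WT lines, although no single gene passed over all genes tested. Adjusted over the list alone 48 of 63 were lower, with a median of -2.65 (-2.59 with genes at 0 set to their bound; camera adjusted p = 1.32e-19, 0.763 with an estimated correlation). Ifit1 differed by -5.16 ± 1.01 (log2, SE), Isg15 by -4.18 ± 0.84 and Ifih1 by -3.14 ± 0.59, each with an adjusted p = 0.158. Of 54 nuclear oxidative phosphorylation genes 34 were higher in hom lines adjusted over the list alone and 0 over all genes, with a median of 0.55 (camera adjusted p = 6.6e-18, 0.693 with an estimated correlation); Atp5h differed by 0.78 ± 0.24 (adjusted p = 0.419). Line E1.4 carried this: the mean log2 CPM of the nuclear oxidative phosphorylation genes was 7.65 in E1.4 against 6.56 and 6.68 in E2.2 and E2.9, and 6.56 to 6.61 in WT lines. The mitophagy receptors Sqstm1 and Optn differed by -0.11 ± 0.17 and 0.03 ± 0.20. The edgeR count was 0, with 1445 genes at an unadjusted p under 0.05, and the count was 35 with DESeq2 and 31 in the compared groups alone, a fit with 319 genes at an unadjusted p under 0.05. Those 1445 were 381 without E1.4, 2633 without E2.2, 2772 without E2.9, and 879, 955 and 872 without WT lines E1.5, E2.1 and E2.7.

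Het lines were not separated from WT lines, and they varied widely among themselves. Isg15 stood at 132 ± 132 CPM in untreated het lines (SD, n = 4) and 131 ± 32.6 CPM in WT lines (SD, n = 3), and Ifit1 under poly(I:C) at 1071 ± 959 and 963 ± 118 CPM. The mean log2 CPM of the interferon-stimulated genes ran from 2.98 in line E2.6 to 6.05 in E2.5 without treatment, and from 4.36 to 7.92 in the same lines under poly(I:C). In edgeR 0 genes passed for het against WT lines in each treatment, with 90, 137 and 64 at an unadjusted p under 0.05 untreated, under poly(I:C) and under AO, and 0 with DESeq2. Without E1.3 these were 201, 394 and 166, without E2.5 176 untreated and 177 under AO, without E2.8 137 and 113, without E2.6 58 untreated, and without WT line E2.7 97 under AO. With no filter they were 267, 282 and 234, and in the compared groups alone 160 untreated. For the interferon-stimulated genes 0 members passed, over all genes and adjusted over the list alone. Its median was 0.10, 0.16 and -0.05, and its mean was above 0 in each treatment, while camera placed the list lower in het lines (adjusted p = 4.97e-08, 1.86e-04 and 8.64e-08), the opposite sign to the mean. With an estimated correlation the adjusted p was 0.974 in each.

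A linear trend over the number of N129D alleles put the interferon-stimulated genes at a median of -1.17 per allele untreated, -1.59 under poly(I:C) and -1.15 under AO. The medians of het against WT lines, given above, were far smaller in size. The trend thus rests mainly on the hom lines and does not show an even step per allele. Adjusted over the list alone 29 of 63 passed under poly(I:C), and 0 in the other treatments. The camera adjusted p was 2.95e-95 under poly(I:C) (0.0563 with an estimated correlation), 3.57e-36 untreated (0.429) and 2.97e-18 under AO (0.763). Over all genes 0 passed in edgeR in each treatment, with 414, 517 and 1495 at an unadjusted p under 0.05, and 1, 17 and 0 with DESeq2. Without het line E2.5 the edgeR counts were 42, 139 and 41, and without WT line E2.1 1 gene passed under poly(I:C). Of the genes at an unadjusted p under 0.05, those under AO were 279 without hom line E1.4 and 2253 without E2.2, and those untreated 255 without E1.4 and 236 without E1.5. With no filter 956 genes untreated and 1064 under poly(I:C) were at an unadjusted p under 0.05.

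The responses themselves were then compared between genotypes. Il6 rose by 4.61 ± 0.69 (log2, SE) in WT lines under poly(I:C) and changed by 1.27 ± 0.65 in hom lines without passing (adjusted p = 0.467), a difference of -3.34 ± 0.95 that did not pass (adjusted p = 1). The response of Isg15, from a lower level in hom lines, differed by 0.44 ± 1.03 and that of Cxcl10 by 0.05 ± 0.92, neither passing (adjusted p = 1). Ifnb1 had no counts in untreated WT lines, so its fold there is only a lower bound. Under poly(I:C) it differed by -5.94 ± 0.92 (log2, SE) between hom and WT lines (edgeR adjusted p = 0.0253). A lack of calls for the difference of response therefore does not show equal induction of every gene. For the interferon-stimulated genes the median difference of the poly(I:C) response was -0.52 (camera adjusted p = 1.01e-04, 0.974 with an estimated correlation). In edgeR 0 genes passed for the response of hom or het against WT lines to poly(I:C) or AO, with 156 and 73 at an unadjusted p under 0.05 for poly(I:C) and 127 and 31 for AO. DESeq2 and the fit with lines as a replicate block also gave 0. With that replicate block the counts at an unadjusted p under 0.05 were 737 and 247 for poly(I:C) and 439 and 134 for AO in hom and het lines, with a smallest adjusted p of 0.116 for hom and 0.171 for het lines under poly(I:C). With no filter they were 362, 287, 363 and 263. For hom lines the counts at an unadjusted p moved to 102 and 91 without E1.5 and E2.7 for poly(I:C), and to 84, 285 and 193 without E2.7, E2.2 and E2.9 for AO.

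Across the genes that passed in WT lines, the log2 responses to poly(I:C) correlated between WT and hom lines with a Pearson r of 0.905 and a Spearman rho of 0.916, and the slope was 0.647; for het lines r was 0.957, rho 0.946 and the slope 0.892. The responses to AO gave r = 0.960, rho = 0.943 and a slope of 0.962 for hom lines, and 0.966, 0.959 and 0.850 for het lines. These correlations are across genes, which are not independent replicates, and they use genes chosen for passing in WT lines; over all genes tested r was 0.541, 0.686, 0.638 and 0.699 in the same order.

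The libraries with a density label asked how crowding changed WT line E1.5. At high density 60 of 61 interferon-stimulated genes were higher and none lower, all 61 adjusted over the list alone, with a median of 2.12 (camera adjusted p = 1.05e-73, 0.116 with an estimated correlation). Untreated, Isg15 stood at 252 CPM at high and 79.8 CPM at low density, and Irf7, a regulator of interferon genes, at 62.9 and 10 CPM. The largest rises included Gbp5 by 3.81 ± 0.24 (log2, SE), Mx1 by 3.58 ± 0.31, Iigp1 by 3.43 ± 0.16 and Tgtp2 by 3.35 ± 0.17. Cyp1a1 changed by -2.80 ± 0.28, Lrp2 by -1.91 ± 0.20 and Ankrd1 by -0.81 ± 0.07.

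Of 19 actin and SRF genes 16 were lower at high density (adjusted p = 0.228 with an estimated correlation), with Acta2 changed by -0.76 ± 0.05, and 18 of 32 G2 and mitosis genes (0.286), 10 of 13 mitochondrially encoded mRNAs (0.286) and 11 of 54 nuclear oxidative phosphorylation genes (0.588) were lower. Among YAP and TEAD targets 10 of 20 were lower and 2 higher (0.648). Of 25 cholesterol synthesis and uptake genes 16 were higher (0.676), with Hmgcs1 up by 0.50 ± 0.06, and 20 of 31 NF-kB and inflammatory genes were higher with 1 lower (0.713), 19 of 37 lysosomal genes (0.23) and 16 of 38 integrated stress response genes (0.69) were higher. Adjusted over the list alone these counts were 17, 23, 10 and 12 lower, 11 lower and 2 higher, then 17 higher, 22 higher and 2 lower, 21 higher and 1 lower, and 19 higher. In total 2177 genes passed, 1108 higher and 1069 lower. These p-values compare 1 culture per treatment and density of a single line, and the high-density libraries were also deeper, at 16474077 to 22756901 counts against 5391426 to 6308011 at low density. The count was 1113 without the untreated libraries and 1303 without the poly(I:C) libraries.

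Markers of other cell types were examined because MEF cultures can hold several. Lyz2, an abundant lysozyme gene of macrophages, stood at 97.7, 83.9 and 39.2 CPM in the untreated, poly(I:C) and AO libraries of hom line E2.9 and at 20.7, 12 and 9.73 CPM in het line E2.6. The receptor gene Csf1r stood at 31.1, 36.5 and 30.4 CPM in E2.9, and both genes were chosen from the list after their values were seen. Of 15 macrophage markers tested 0 passed between hom and WT lines in edgeR in any treatment, although the median log2 difference was 4.54, 4.83 and 4.83 with genes at 0 set to their bound. Line E2.9 alone made these medians, and Lyz2 stood at 0 CPM untreated in the hom lines E1.4 and E2.2. No marker list held a gene that passed between hom and WT lines in any treatment over all genes tested; adjusted over the list alone 1 adipocyte marker was lower untreated and 2 were lower under poly(I:C). Under AO in WT lines 1 of 6 adipocyte markers rose and 0 of 7 chondrocyte, 5 endothelial, 5 epithelial, 29 Hox, 6 neural and glial, 5 skeletal muscle, 8 smooth muscle, 5 sex-linked and 15 macrophage markers passed. Erythroid genes were too few among those tested, and Epor reached 2.74 CPM in 1 library.

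**Figure D4:**
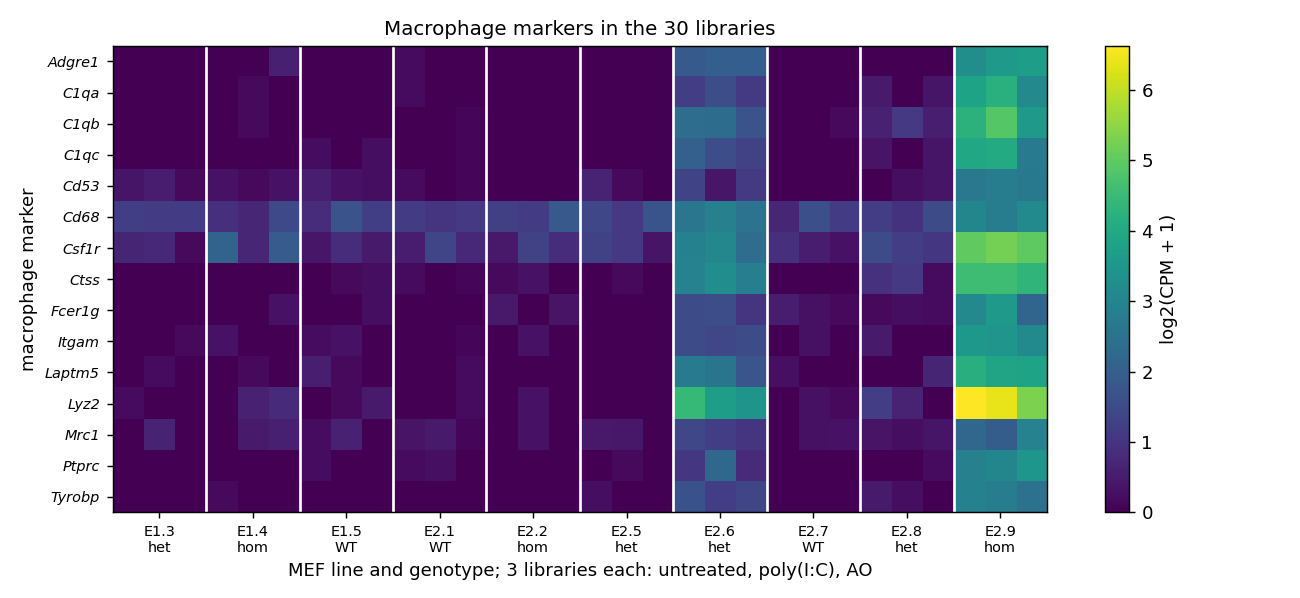
Heat map of macrophage markers (y axis) in the 30 libraries (x axis, ordered by line, with 3 treatments per line), coloured by log2(CPM + 1). All 3 libraries of hom line E2.9 stood highest for 14 of 15 markers, followed by het line E2.6.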

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

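The tests of macrophages, of other cell types and of the hom genotype in line E2.9, and the tallies of markers in lines E2.6 and E1.4, were chosen only after the result was seen.

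Het line E2.6 stood far from the other het lines in the integrated stress response. Untreated, the mean log2 CPM of the integrated stress response genes was 4.28 in E2.6 and 5.89 to 6.18 in the other het lines, a gap of 0.846 of the whole range. Trib3 stood at 3.04 log2 CPM against 6.46 to 6.83 (gap 0.902), Chac1 at 1.87 against 5.39 to 5.84 (0.886), Asns at 6.62 against 8.13 to 8.31 (0.893) and Ddit3 at 4.41 against 6.12 to 6.34 (0.884). Cdkn1a stood higher, at 7.58 against 5.57 to 5.82 (0.876), as did the actin and SRF genes at 9.18 against 8.4 to 8.47 (0.915).

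The same line stood apart under both treatments. Under poly(I:C) the gap was 0.896 for the integrated stress response genes, 0.855 for Trib3, 0.894 for Asns and 0.842 for Cdkn1a. Under AO it was 0.831 for the integrated stress response genes, 0.866 for the aminoacyl-tRNA synthetases, 0.853 for the actin and SRF genes, 0.97 for Atf4 and 0.854 for Asns. Line E2.6 also held macrophage transcripts and the highest level of 7 of 11 chondrocyte, 4 of 11 endothelial and 4 of 8 smooth muscle markers detected. Among these were Col2a1 (185 CPM, mean 81), Lmod1 (57.1 CPM, mean 9.06) and Myh11 (18.7 CPM, mean 2.06), while Acta2 and Des peaked in hom line E1.4. Apart from Col2a1, the chondrocyte markers that peaked in E2.6 were near the floor, at 3.97 CPM (Comp) or less. The better expressed Sox9 and Acan peaked in WT line E2.7 and hom line E2.2. No explanation was tested for this line.

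Far lines were sought in het groups alone, since groups of 3 lines are not tested this way. Hom line E1.4 stood apart by other measures: under AO the chi-square per degree of freedom was 57.5 to E2.2 and 65.7 to E2.9, against 5.61 between those lines and at most 38 among het lines. Untreated it was 43.1 and 42.7, against at most 30.6 among het lines. Under poly(I:C) it was 18.4 and 21.6, within the het range of 14.2 to 46. Of 39 Hox genes detected, 13 peaked in E1.4, against 8 in WT line E1.5 and 7 in het line E2.6. Those in E1.4 included Hoxb2 (25.8 CPM, mean 4.88) and Hoxa3 (11.8 CPM, mean 2.18). A cause of this difference between lines was not tested. Het line E2.5 stood high in the interferons and antiviral chemokines untreated (gap 0.846) and, under poly(I:C), in the dsRNA sensing and TBK1 signalling components (0.914) and Tnfaip3 (0.963, at 8.43 log2 CPM against 7.63 to 7.66). Het line E1.3 under poly(I:C) stood low in the mitochondrially encoded mRNAs (0.842) and the fibroblast extracellular matrix genes (0.856). In all, 21 of 177 groups of values had a line this far out, and chance gives about 1 in 20. The lists and genes overlap and treatments share lines, so these are not independent.

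Opposite responses were sought over 59 lists and genes, in each treatment and for het and hom against WT lines. In 2 cases, each a single gene, every WT line moved one way and every hom line the other. With so few lines per group and so many searches, such cases can arise by chance. Fgf21 under poly(I:C) changed by -0.54 in WT and 0.69 in hom lines, a difference of 1.23. Irf7 under AO changed by 0.30 in WT and -0.77 in hom lines, a difference of -1.08. These opposite directions were not tested as such, and the adjusted p for the difference of response was 1 for each gene.

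Macrophage transcripts marked hom line E2.9. Of 15 macrophage markers, 14 stood higher in all 3 libraries of E2.9 than in each of the other 27 libraries, a share of 0.933, and Lyz2 reached 97.7 CPM untreated. The 15 were those kept by the filter on low counts, which a marker can pass through the 3 E2.9 libraries alone. The share of 0.933 is therefore partly set by the filter. Without it, all 16 macrophage markers detected peaked in a library of E2.9. Markers of other cell types argue against a broad change of cell type, since 1 of 43 did so, a share of 0.023. The hom genotype as the source is argued against by lines E1.4 and E2.2, where 0 of 15 markers stood higher in all 6 libraries than in every WT library. Macrophages in the culture of E2.9 are a candidate explanation, found and tested on the same data, and het line E2.6 held the same markers at a lower level (Lyz2 20.7 CPM untreated).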

How the results depend on the processing

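The settings without pairs of lines were chosen only after the result was seen. RLE factors kept every count of genes within 1.5 times, and of 1334 values of named genes 1333 kept their direction and side of the threshold. With no filter on low counts the genes passing under poly(I:C) were 170 in WT, 309 in het and 37 in hom lines, under AO 645 in WT and 1116 in hom lines, and for hom against WT lines 0 untreated and 5 under poly(I:C). DESeq2 gave 673 in WT and 349 in hom lines under poly(I:C), 33, 107 and 35 for hom against WT lines untreated, under poly(I:C) and under AO, and 1 and 17 for the trends untreated and under poly(I:C); of the named genes' values 1274 kept their side, 41 newly passed and 2 no longer passed. The replicate block gave 2077, 2368 and 1274 under poly(I:C) and 3045, 3663 and 3932 under AO in WT, het and hom lines. By construction it removes the spread between lines; it moved no other count of genes that passed by over 1.5 times and ended no call, while 91 values of named genes newly passed and 594 kept their side. A fit on the compared groups alone gave 1578, 102 and 0 under poly(I:C), 2270 in WT and 3 in hom lines under AO, and 52, 110 and 31 for hom against WT lines. With E1 or E2 as a covariate hom against WT lines gave 0 untreated and 52 under poly(I:C), and with Y-linked expression 0 untreated. Over all genes tested the correlations of responses with WT were 0.541 (poly(I:C), hom), 0.686 (poly(I:C), het), 0.638 (AO, hom) and 0.699 (AO, het). With an estimated correlation 6 of 136 camera calls held. Apart from the block, the cause was not tested.

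Leaving out 1 line at a time uses fewer samples. The lowest and highest counts were 9 and 59 in WT, 121 and 788 in het and 0 and 559 in hom lines under poly(I:C), and 196 and 259, 515 and 1517, and 744 and 1632 under AO. For hom against WT lines they were 0 and 0 untreated, 0 and 3 under poly(I:C) and 0 and 0 under AO. For the trends they were 0 and 42, 0 and 139, and 0 and 41, the highest without het line E2.5, and for density 1113 and 1636. Correlations ran from 0.878 to 0.904 (poly(I:C), hom), 0.946 to 0.961 (poly(I:C), het), 0.934 to 0.966 (AO, hom) and 0.955 to 0.968 (AO, het). The log2 value of Tnfaip3, high vs low density in WT E1.5, was 0.09 and did not pass; it ran from -0.43 without the poly(I:C) libraries, where it reversed, to 0.39 without the AO libraries.

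Without E1.4 and E2.6, 2361 and 1281 genes passed in het and hom lines under poly(I:C), 2988 in het lines under AO and 0 for untreated hom against WT lines. Without E2.9 and E2.6, 30 passed in hom lines under poly(I:C), 1101 in hom lines under AO and 0 for untreated hom against WT lines. The 2 alternatives meant for data without counts do not apply and were not run. At depths of 3689177 to 14879261 counts, folds of Ifnb1 against untreated lines are known only as lower bounds.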

Other observations

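The tests of cell density and of the chromosome segment around Tbk1 were chosen only after the result was seen.

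Xist, the RNA that coats the inactive X chromosome, stood lower under poly(I:C) in 4 of the 5 lines that expressed it strongly, and no comparison of groups passed. Each genotype mixed lines with strong and with little or no Xist, so those comparisons say little about the fall within lines. Xist stood at 900 CPM untreated and 335 CPM under poly(I:C) in het line E1.3, at 900 and 321 CPM in WT line E1.5, at 748 and 261 CPM in WT line E2.7 and at 836 and 271 CPM in hom line E2.9. Under AO it stood at 973, 960, 781 and 821 CPM in the same lines. Hom line E1.4 stood at 284, 280 and 310 CPM untreated, under poly(I:C) and under AO. Het line E2.8 had 69, 11 and 60 Xist counts.

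Xist stood lower in E1.4 than in the other strongly expressing lines untreated and under AO. Under poly(I:C) it did not, at 280 CPM against 261 to 335 CPM. The lower level in E1.4 could follow from loss of the second X chromosome in part of the cells. Such a loss alone does not account for the flat level of Xist under poly(I:C) in this line. Its fold was 0.987, against 0.324 to 0.372 in the other lines that expressed it strongly. The mean log2 CPM of 5 genes that escape X inactivation was 7.22 in E1.4, a difference of -0.31 from the lowest of the other Xist-positive lines. The lines with few or no Xist counts, E2.8 among them, stood at 7.18 to 7.22. E1.4 thus stood within the range of those lines although it kept Xist at 284 CPM untreated, and the extent of a loss was not tested. A lower share of nuclear long non-coding RNAs in the E1.4 libraries stays open, since 2 of 6 such RNAs stood lowest in untreated E1.4.

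For the genes lower in hom than in WT lines, a lower cell density of the hom cultures is argued against as the whole cause in untreated cells. There 100 genes lowered at high density differed by -0.055 between hom and WT lines. Their share relative to that of the interferon-stimulated genes was -0.05, from -0.113 to 0.012 when lines were left out. The same test was not run under poly(I:C), where 25 genes passed. The density effect comes from line E1.5 alone, where it moved the interferon-stimulated genes by a median of 2.12. The sources used here give neither the density of the 30 other libraries nor what high and low mean, so a smaller part for density stays open. An expression difference carried by the chromosome segment around Tbk1 stays open: 0 of the 25 genes that passed under poly(I:C) lay within 20 Mb of Tbk1, where the share of genes tested (141 of 13364) gives 0.264, so a count of 0 decides nothing. An effect of N129D itself stays open, as does any difference between embryos that came with the genotype.

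Other splits of the same libraries were counted in fits on the compared groups alone. In het lines the real split gave 102 genes under poly(I:C) against 54 for the highest other, and 1461 under AO against 46, each in 1 of 35 splits. Treated and untreated libraries of a line are paired, and the 8 splits that part as many pairs, the real one included, are too few for a share under 0.05. The highest other of these was 0, as it was among the 4 such splits in WT and in hom lines. With 10 splits a share under 0.05 cannot be reached. There the real split gave 1578 (poly(I:C), WT), 0 (poly(I:C), hom), 2270 (AO, WT), 3 (AO, hom), 1696 (density) and 52, 110 and 31 (hom against WT lines untreated, under poly(I:C) and under AO), and the highest other gave 0.

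Where the real split gave 0 genes, every split gives at least as many by construction, and the count says nothing about chance. This held for poly(I:C) in hom lines and the differences of response between hom and WT lines (10 of 10 splits, highest other 0), and for the differences of response between het and WT lines (35 of 35, highest other 0). It held too for het against WT lines (35 of 35, highest others 4, 5 and 8) and for the trends (100 of 100, highest others 10, 14 and 1).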
